A study of Vitis vinifera with 15 samples.

How the data were processed

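Total RNA of grapevine berry pericarps (skin and flesh) was hybridised to 1-colour (Cy3) Agilent expression arrays, 1 array for each of 15 samples. Per the labels' protocols, the berries were of the cultivar Müller-Thurgau, had been withered after harvest, and were injected with conidia of Botrytis cinerea strain B05.10, the fungus of noble rot, or with water. The labels give 5 groups of 3 samples each: untreated berries at day 0, water-injected and infected berries at day 5, and water-injected and infected berries at day 10. They call the samples of a group biological replicates, pools of 65 berries at day 0 and of about 50 berries later. The series' design text calls the uninfected berries of another cultivar, while the sample labels name 1 cultivar throughout; groups were taken from the sample labels.

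Per the file headers, the arrays were scanned and the spots read with Agilent Feature Extraction, whose version the submitters' processing notes give as 10.5.1. The intensity values used were the processed signal of each spot, which per the file headers is the spot's brightness after background subtraction on that array, not normalized between arrays. The authors also deposited a value table with intensities of 24085 probes. Its unit is linear: each column was a multiple of the processed signal of 1 scanner file, with the array's 75th percentile set to about 678, and its values were neither centred nor logged. Column medians lay between 265.19 and 286.47. How these probes were chosen is not given in the sources used here. In this table the 3 columns of infected berries at day 5 are multiples of the scanner files of water berries at day 10, and the reverse, while the other 9 columns match their own scanner files. The scanner files, each tied to its sample by the series' own record, were the source of all main values. The value table served as an alternative, both as given and with its columns matched to the scanner files. Matched columns are multiples of those files, and 23154 of the table's probes were also tested here. Like counts with matched columns are thus no independent check.

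From the scanner files, log2 of the processed signal minus the 75th percentile of the 34369 non-control spots of that array was computed in R 4.3.3, and every level and change is relative to that percentile. Every ID had 1 probe, so the planned mean over probes of a gene was void. No spot was saturated. Spots marked as outliers, 4 to 36 per array, were kept. Probes well above background on all 3 arrays of at least 1 group were tested, 23454 in all. limma 3.58.1 (lmFit and eBayes) fitted group means over the 15 arrays, so that all groups share an estimate of the spread, and each of 7 comparisons was called at a Benjamini-Hochberg adjusted p under 0.05, with changes of at least 2-fold counted too. Where a probe was well above background on no array of a group, a fold between 2 groups is given as a lower bound: the mean of the brighter group against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own. A probe not well above background can lie above that lowest signal, so these bounds are approximate and "at least" is meant in this sense. Differences between days in the infection effect are fitted values, with no bound. No count gives a depth for arrays; the number of arrays limits the precision.

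The files pair no ID with a gene name, and 0 of the IDs matched the 29591 genes of the RefSeq table given. Of the 34369 IDs, 29798 begin with VIT, 4392 with XLOC and 179 with neither; the sources used here do not say what the prefixes mean. Before the data were examined, 38 gene lists, the groups, the comparisons, the other settings to try and the rule for named genes were fixed. Of these lists, 37 were defined by words in gene descriptions and could not be filled, among them the markers of seed, of skin and of conserved genes meant to show other tissue or fungal RNA. Only the list of stilbene synthases, fixed as 2 ranges of VIT IDs from general knowledge of the grapevine gene numbering and not from the files, could be tested. It had 49 IDs on the array, of which 47 were tested. limma's camera with a preset correlation of 0.01 compared it with all other genes. The correlation estimated from the data was 0.739. The p-values at the preset thus treat the members as far more independent than they were. Genes of this family lie in tandem copies of similar sequence, so probes can share signal and single members are uncertain; they are described as a group. The rule took the 6 largest rises and falls past the threshold in each comparison of infection, and the 3 largest against untreated berries, among genes above background in a group compared, with an informative description and, for comparisons of 2 groups, with no overlap between their arrays; it also took the largest changes in each list. With no descriptions that condition could not be applied, so the 2 largest rises and falls by the rest of the rule were taken instead, IDs are printed for the comparisons of infection alone, and members of the list are not named.

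Of 10 spike-in control probes with E1A names, 7 tracked one another and were averaged as a reference of each array; the other 3 were left out after the values were seen, 2 for lying near background and 1 for following the signal of the other spots. Array measures were compared between infected and water berries by an exact two-sided permutation test within days, with 400 splits and a smallest possible p of 0.005. The file headers give 4 scans on 2 days. Each scan held arrays of 3 or 4 groups, so scan was tried as a block and differences were also taken within scans. Of the 6 group pairs checked, only untreated and day-5 water berries had every same-numbered pair of deviations from the group means correlated over 0.1 (0.21 to 0.32), and these pairs also shared scans. Water and infected berries of day 10 correlated at 0.07 to 0.28, each pair above the mean of pairs with other numbers. Of these, the pairs numbered 2 and 3 shared a scan (0.28 and 0.24) and the pair numbered 1 did not (0.07). Over the group pairs checked, same-numbered pairs that shared a scan correlated at 0.06 to 0.35, and those that did not at -0.22 to 0.14. The labels give the numbers no meaning beyond naming the sample.

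The fit was tested on simulated data with the real means and spreads of the 23454 genes and 200 genes changed in infected berries at day 5. For infected against water at day 5, 78% of the genes changed by 2 on the log2 scale and 42% of those changed by 1 were recovered, with 9 unchanged genes called. For the difference of the infection effect between days, 55% and 27% were recovered. The real comparison at day 5 called 10907 genes, and the adjusted threshold depends on the share of genes changed. The simulated genes were also drawn independently. These shares therefore do not give the recovery in the real comparisons. A pass mark for recovery set before this test was not met, and was replaced after it by unbiased estimates and few false calls. The other settings fixed in advance were normexp background correction with an offset of 50, quantile normalization, scaling on the median of probes detected on all arrays, the value table as given, no filter, only the 15879 probes detected on all 15 arrays, eBayes with trend and robust settings, only the groups of a comparison, the replicate number and the scan as blocks, array weights, leaving out each array, a threshold of 0.01, an unmoderated model, and camera with an estimated correlation. The mean signal that normexp was to use has no column in the scanner files used here, so the median signal took its place. Figures were drawn with matplotlib 3.10.9.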

Results

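Gene expression in withered grapevine berries was measured on 15 arrays, with 3 pools of berries in each of 5 groups: untreated berries at day 0, and water-injected or Botrytis-infected berries 5 and 10 days after injection. Per the labels, day 5 was the first stage of noble rot, the slow infection of ripe berries used for sweet wines, and day 10 the stage at which the whole berry had turned brown. The share of spots well above background was 67.5% ± 3.08 (SD, n = 3) in untreated berries, 69.8% ± 7.61 in water berries and 62.9% ± 9.26 in infected berries at day 5, and 73.3% ± 5.97 in water berries and 56.9% ± 3.77 in infected berries at day 10. Arrays of 1 group correlated at 0.962 or higher across the genes tested.

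The first principal component held 66.9% of the variance. All 6 infected arrays lay at positive values of it, with day 10 beyond day 5, and all 9 uninfected arrays at negative values. The second component held 12.7% and ran from untreated berries to water berries of day 10.

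**Figure D1:**
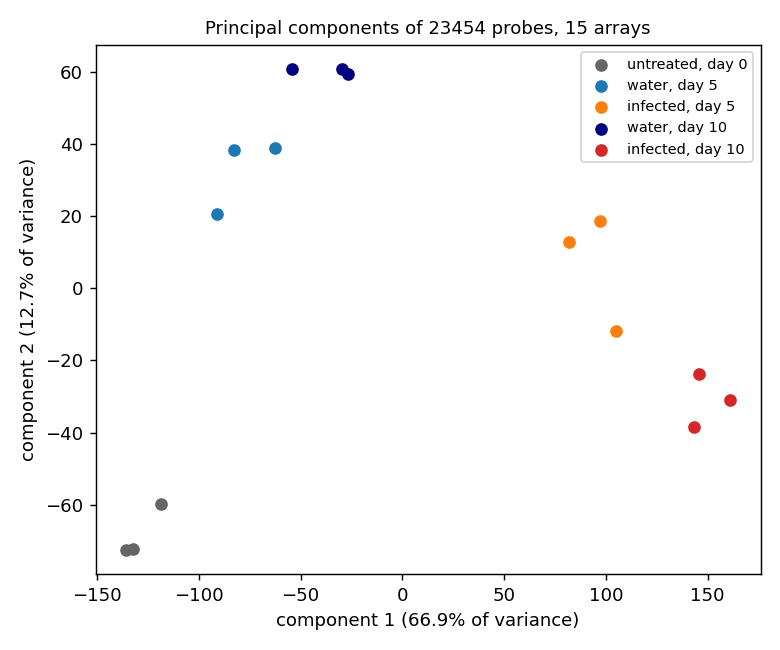
Position of the 15 arrays on the first 2 principal components of the normalized log2 signals, 1 point per array, coloured by group; the axes give each component's share of the variance. Infected arrays lie between 81.7 and 161 on component 1 and uninfected arrays between -136 and -26.6.

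The signal of berry genes fell relative to the spike-in control probes on infected arrays. The array's 75th percentile minus the mean of 7 spike-in probes was -1.37 ± 0.46 (log2, SD, n = 3) in water berries and -2.97 ± 0.55 in infected berries at day 5, and -1.56 ± 0.57 and -3.93 ± 0.61 at day 10, against -1.58 ± 0.20 in untreated berries. Across both days infected arrays were lower by a mean difference of -1.98 (exact two-sided permutation test within days, 6 infected and 6 water arrays, p = 0.005, the smallest it can give; p = 0.00625 after Benjamini-Hochberg adjustment over 5 measures). In each scan that held a pair of 1 day, the infected array was the lower of the pair: -2.82 against -1.68 in scan 1, -2.51 against -0.84 in scan 2, -4.16 against -2.04 in scan 3 and -4.38 against -1.73 in scan 4. Of the 10 spike-in probes, 3 were left out after the values were seen, 1 of them for following the signal of the other spots. That choice can enlarge this difference, which is not given here with the 3 kept. The changes described next are relative to each array's 75th percentile. Scaled to the spike-in probes, a choice made after seeing the data, the median gene was shifted by -1.64 in infected against water berries at day 5 and by -2.30 at day 10, and most genes called were lower.

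**Figure D2:**
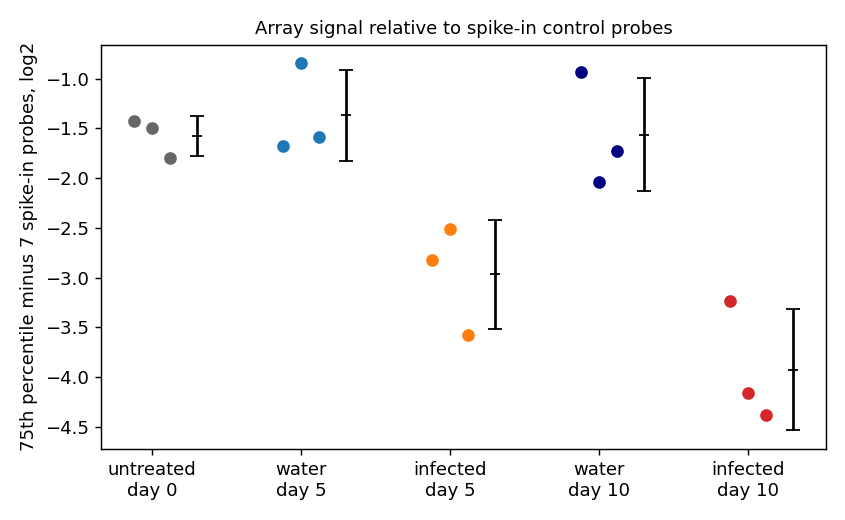
Log2 of the array's 75th percentile signal minus the mean log2 signal of 7 spike-in control probes, 1 point per array, with the group mean and SD (n = 3). All infected arrays lie below all water arrays of the same day.

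The comparison of infected with water-injected berries of day 5 asks how the berry's transcripts differ at the onset of noble rot. Stilbene synthases, the enzymes that make resveratrol, a defence compound of grapevine, rose as a group: 45 of the 47 IDs in the ranges taken for this family rose, 1 fell and 1 did not pass the test. Their median change was 3.39 on the log2 scale, and the members' changes ran from -1.76 to 4.50, the lowest on a probe above background on 1 of the 3 infected arrays. All 49 IDs of these ranges on the array together gave 4.60% ± 0.77 (SD, n = 3) of its signal in infected berries. They gave 0.62% ± 0.33 in water berries and 0.07% ± 0.04 in untreated berries of day 0. Adjusted over the list alone, the same numbers of members were called, 45 up and 1 down. The list stood above other genes (limma's camera, adjusted p = 4.11e-21 over the single list tested), with adjusted p = 0.0826 with an estimated correlation, so that call was lost. The median was 4.54 within scan 1 and 3.20 within scan 2, 3.50 with scan as a block, and 1.79 when scaled to the spike-in probes.

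In infected berries of day 5, XLOC_007374 was at 4.83 ± 0.18 (log2 relative to the 75th percentile, SD, n = 3) and well above background on no array of water berries of that day, at least 2293-fold higher (limma, adjusted p = 7.27e-07). VIT_03s0088g00010 was at least 1409-fold higher (adjusted p = 2.57e-07), again well above background on no water array of that day. Of the genes that fell, VIT_02s0025g01090 was well above background in water berries and on none of the infected arrays, at least 9.23-fold lower (adjusted p = 2.16e-07). VIT_18s0041g01220 fell by 3.94 ± 0.22 (SE, adjusted p = 1.73e-07) on the log2 scale. It was above background on 1 of the 3 infected arrays, so this size rests in part on unmeasured levels. The files give none of these IDs a name.

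Of 23454 genes, 10907 changed at day 5 (limma, adjusted p under 0.05), 5139 up and 5768 down. At least 2-fold, 3415 rose and 2199 fell, 5614 in all. Among the 15879 probes well above background on all 15 arrays, 2907 changed at least 2-fold. With a common floor, chosen after seeing the data, 3739 did. With quantile normalization falls were the majority of changes of at least 2-fold, 2770 up and 3001 down. The arrays of the groups did not overlap for 58.7% of genes, where chance gives 10%. Among the 5139 rises, 508 were on probes not well above background on all infected arrays. The share of rises among calls was 47.1%, against 36.3% with quantile normalization and 5.45% when scaled to the spike-in probes, and rises were the majority with normexp (52.3%), without a filter (58.0%), scaled on the median of probes detected on all arrays (50.4%) and with the value table's columns as given (87.4%). With the value table's columns as given, in which the arrays of infected berries at day 5 and of water berries at day 10 change places, the same comparison called 815 genes; with columns matched to the scanner files it called 10885. With the columns as given, none of the 4 IDs named for day 5 was called (adjusted p from 0.186 to 0.959).

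The same comparison at day 10 describes infected berries that, per the labels, had turned brown as a whole. Of the 47 stilbene synthase IDs, 34 rose, 1 fell and 12 did not pass the test, with a median of 1.25 on the log2 scale, but the direction depended on the scaling: 6 rose with quantile normalization (median 0.43), and scaled to the spike-in probes 1 rose and 26 fell (median -1.11). The number that rose was 20 without water replicate 1 of day 10, 21 without infected replicate 3 of day 10 and 9 with array weights. The 1 that fell was well above background on no infected array of day 10. Adjusted over the list alone, 40 rose. All 49 IDs of the ranges on the array gave 4.51% ± 0.78 (SD, n = 3) of the signal in infected and 2.88% ± 0.43 in water berries. The list stood above other genes (limma's camera, adjusted p = 1.47e-05), and with an estimated correlation the adjusted p = 0.397. That call was also lost with the value table's columns as given. The median was 0.68 within scan 3, 1.63 within scan 4 and 1.23 with scan as a block.

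XLOC_007374 rose again, by 10.57 ± 0.90 (SE, limma, adjusted p = 9.67e-07) on the log2 scale. Of the 3 water arrays, 2 now measured it above background, so this size rests in part on an unmeasured level. VIT_07s0031g00870, well above background on no water array of either day, was at least 363-fold higher (adjusted p = 1.48e-07). VIT_14s0030g02310 was well above background on every array of the other 4 groups and on no infected array of day 10, at least 41.4-fold lower (adjusted p = 2.33e-08). VIT_15s0046g00570 fell by 5.94 ± 0.27 (SE, adjusted p = 9.67e-09), from 1.75 ± 0.30 (SD, n = 3) in water berries to -4.18 ± 0.69 in infected berries. It was above background on 1 of the 3 infected arrays, so this size rests in part on unmeasured levels.

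At day 10, 13992 genes changed, 7243 up and 6749 down. At least 2-fold, 4763 rose and 3322 fell, 8085 in all. Among the 15879 probes well above background on all 15 arrays, 4668 changed at least 2-fold. With quantile normalization 3518 rose and 5113 fell at least 2-fold. Among the 7243 rises, 977 were on probes not well above background on all infected arrays. Of the IDs beginning with XLOC, 31.4% rose at day 5 and 49.3% at day 10, and of those beginning with VIT 21.1% and 29.4%. With a floor common to all arrays, added after seeing the data, the shares were 18.0% and 17.8% at day 5 and 40.7% and 27.9% at day 10, and the differences in share were not tested. The share of rises among calls was 51.8%, against 74.2% with normexp, 70.6% without a filter, 37.2% with quantile normalization, 43.6% with the value table's columns as given, 48.2% where infected or water berries, whichever were higher, had to be above background on all arrays, and 2.41% when scaled to the spike-in probes. With the value table's columns as given the comparison called 3817 genes, and with columns matched to the scanner files 14079; as given, XLOC_007374 and VIT_07s0031g00870 were not called (adjusted p = 0.785 and 0.207). Without a filter on dim probes it called 22521 of 34369.

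The infection effect at both days was compared gene by gene; the 2 comparisons share no arrays. Of the genes called, 4375 rose at both days and 4899 fell at both, where independent lists of these sizes would share 1587 and 1660, and 54 were called in opposite directions. Of the genes that rose at day 5, 85.1% also rose at day 10. Across genes, which are not independent replicates, the changes correlated at r = 0.828 (Spearman's rho 0.854). With the value table's columns as given, 68 genes were shared in direction, and scaled to the spike-in probes 343 rose and 17164 fell at both days.

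**Figure D3:**
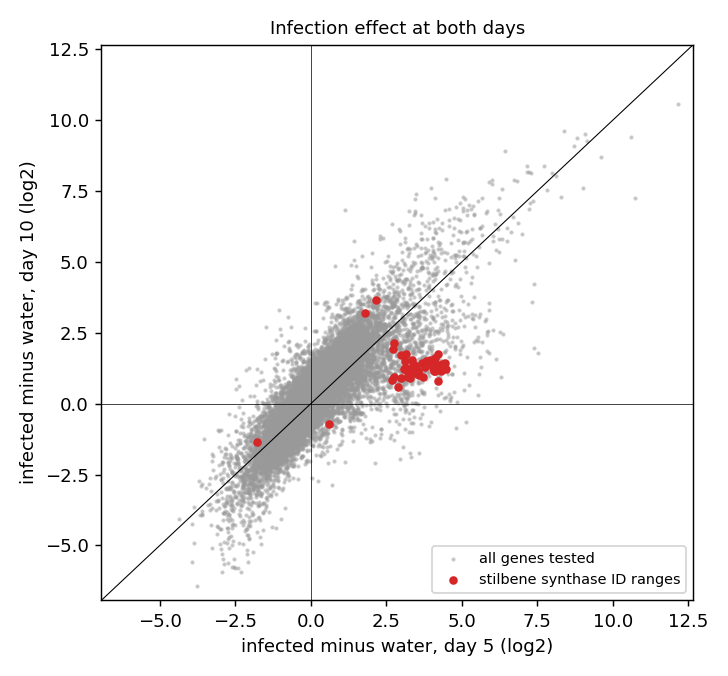
Log2 change of infected against water berries at day 5 (horizontal) and day 10 (vertical) for 23454 genes, in grey, with the 47 stilbene synthase IDs in red and the line of equal change; values are relative to each array's 75th percentile. The stilbene synthases have a median of 3.39 at day 5 and 1.25 at day 10; scaled to the spike-in probes, the median at day 10 is -1.11.

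The infection effect itself differed between the days, by a test of the difference, for 1610 genes (limma), 605 with a larger and 1005 with a smaller value at day 10. Values keep their sign, so a deeper fall counts as smaller. Of 47 stilbene synthase IDs, 30 had a smaller and 1 a larger infection effect at day 10, with a median difference of -2.28 (limma's camera, adjusted p = 1.97e-22, and with an estimated correlation adjusted p = 0.0742). The 30 became 19 and 13 without water replicates 1 and 2 of day 5, 14 without infected replicate 1 of day 5, 12 and 16 without water replicates 2 and 3 of day 10, 19 without infected replicate 2 of day 10, and 17 with array weights or without a filter. Of 100 groupings of the arrays within days, 15 gave a list median as large, the real one included. Such groupings still hold part of the infection effect, so this count can neither exclude chance nor speak for it. Array medians in infected berries were 6.39 ± 0.30 (SD, n = 3) at day 5 and 6.53 ± 0.32 at day 10, and in water berries 2.52 ± 1.00 and 5.29 ± 0.28; these are relative to the 75th percentile, which in infected berries stood lower against the spike-in probes at day 10, and the infected groups were not compared by a test. VIT_18s0001g12900 had a smaller infection effect at day 10 (adjusted p = 0.000381), with levels of 1.31 ± 0.21 (SD, n = 3) and 0.63 ± 0.39 in infected berries at days 5 and 10, and -6.24 ± 1.11 and -1.17 ± 0.19 in water berries; only 2 of the 3 water arrays of day 5 measured it above background, so its fitted difference rests in part on an unmeasured level. VIT_09s0002g02800 had a larger infection effect at day 10 (adjusted p = 7.73e-05), with a level of -0.25 ± 0.17 (SD, n = 3) in infected berries of that day. It was well above background on 0 of the 3 water and 1 of the 3 infected arrays of day 5 and on 2 of the 3 water arrays of day 10, so its fitted difference rests on unmeasured levels, and with normexp the call was lost (adjusted p = 0.124).

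Of the 605 genes with a larger value at day 10, 348 rose at both days and 199 rose at day 10 alone by these calls. Of the 1005 with a smaller value, 374 fell at both days, further at day 10, and 95 fell at day 10 alone. Another 269 rose at both days, less at day 10, 231 rose at day 5 alone, and 36 rose at day 5 and fell at day 10. The count was 3188 with scan as a block, 455 with normexp and 678 when scaled to the spike-in probes, and 896 without water replicate 2 of day 5, 1023 and 989 without water replicates 2 and 3 of day 10. The share with a larger value was 37.6%, against 24.4% with normexp, 26.0% with quantile normalization, 48.9% with scan as a block, 50.7% with a common floor and 3.84% when scaled to the spike-in probes.

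**Figure D4:**
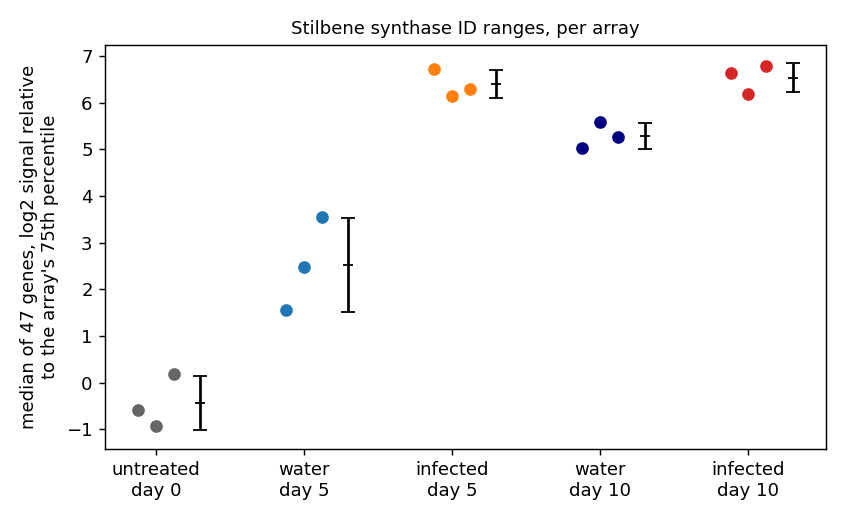
Median log2 signal, relative to the array's 75th percentile, of the 47 tested stilbene synthase IDs, 1 point per array, with the group mean and SD (n = 3). Water berries stand at 2.52 at day 5 and 5.29 at day 10, and infected berries at 6.39 and 6.53; scaled to the spike-in probes, infected berries of day 10 lie below water berries by a median of 1.11 (-1.11).

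Water-injected berries were compared with untreated berries of day 0 as the background of incubation and injection. Stilbene synthases rose without the fungus: 43 of 47 IDs rose at day 5 and none fell, with a median of 3.06, and 45 rose at day 10, with a median of 5.51. The list stood above other genes at both days (limma's camera, adjusted p = 2.12e-29 and 8.73e-42), and these calls held with an estimated correlation (adjusted p = 0.0440 and 0.0197). In all, 5697 genes changed at day 5, 3042 up and 2655 down, and 6958 at day 10, 3345 up and 3613 down. At least 2-fold, 1802 rose and 711 fell at day 5, and 2205 rose and 915 fell at day 10. Scaled to the spike-in probes, the splits of all calls were 1408 up and 172 down, and 1625 up and 327 down, with the median gene shifted by 0.14 and -0.11. At day 5 rises were 53.4% of calls, but between 45.8% and 49.6% with normexp, only the groups compared, scan as a block, array weights, a common floor or only probes detected on all arrays, and at day 10 they were 48.1%, but 52.9% without a filter, 55.9% at a threshold of 0.01, and between 50.6% and 54.4% without any 1 of the 6 arrays compared. The day-5 count was 11379 with array weights, 3678 with normexp and 4069 without water replicate 2 of day 5; the day-10 count was 13327 with the value table's columns as given.

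Infected berries were also compared with untreated berries. At both days 46 of the 47 stilbene synthase IDs rose and 1 fell, with medians of 6.62 and 6.69 (limma's camera, adjusted p = 1.30e-26 and 4.84e-21); with an estimated correlation, adjusted p = 0.0538 and 0.0830. In all, 13312 genes changed at day 5, 5849 up and 7463 down, and 15854 at day 10, 7447 up and 8407 down. At least 2-fold, 4138 rose and 3221 fell at day 5, and 5593 rose and 4666 fell at day 10, so rises were then the majority. That majority depended on the scaling. With quantile normalization, 3474 rose and 4194 fell at least 2-fold at day 5, and 4363 rose and 6515 fell at day 10. Scaled to the spike-in probes, the splits of all calls were 1816 up and 15848 down, and 1468 up and 18588 down. At day 5 the share of rises was 43.9%, against 53.1% without a filter, and at day 10 47.0%, against 64.2% with normexp, 65.6% without a filter and 35.7% with quantile normalization. With the value table's columns as given, 6901 genes were called at day 5.

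The 4 comparisons with untreated berries share their 3 arrays. At day 5, 2258 genes rose and 2116 fell in both infected and water berries, where independent lists would share 759 and 845. The correlation across genes was 0.64, beside 0.50 in simulated groups without effects, and the covariance 0.785, beside 0.0568. At day 10, 2683 rose and 2792 fell in both, where independent lists would share 1062 and 1295, with a covariance of 1.29 beside 0.0574. The shared arrays are too few to divide between the comparisons.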

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

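The tests of explanations in this part were all chosen after the results they bear on had been seen; the counts over other splits of the arrays were planned.

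The infection effect differed between day 10 and day 5 for 1610 genes and, for stilbene synthases, by a median of -2.28. Of the 4 IDs named for this difference, VIT_09s0002g02800 had a fitted difference of 5.68, VIT_00s0480g00070 of 4.36, VIT_01s0010g01970 of -5.78 and VIT_18s0001g12900 of -5.74; each was not well above background on some of the arrays compared, so that these fitted values rest in part on unmeasured levels and are neither sizes nor bounds. The calls of VIT_00s0480g00070 (adjusted p = 0.0308) and VIT_01s0010g01970 (adjusted p = 0.0311) were lost without 1 array in 10 and 7 of 15 cases, with adjusted p up to 0.0743 and 0.0810. Of 100 splits drawn from the 200 that regroup arrays within days, 10 gave as many genes, the real one included, and the highest other count was 10553. All 9 other splits with as many genes kept infected and water arrays apart at 1 or both days, so they carry the infection effect of a day into the difference. Splits that mixed the arrays of both days gave 0 genes, so this count can neither exclude chance nor speak for it. For the stilbene synthase median, 15 of the 100 splits were as large, the real one included, with a highest other of 3.82. Of these 14 others, 10 kept a day apart and 4 mixed the arrays of both days, with medians up to 2.63 beside the real size of 2.28 (-2.28). Mixed splits still hold part of the infection effect: within 1 day their medians reached 1.74 at day 5 and 0.86 at day 10. They are thus no reference without a difference, and this count can neither exclude chance nor speak for it.

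The value table's columns for infected berries of day 5 and water berries of day 10 hold each other's arrays. All 6 interchanged columns match the scanner file of the same replicate number in the other group, which is what 2 whole blocks changing places when the table was assembled would give. The other reading is that the scanner files were attached to the wrong samples. The arrays filed as infected at day 5 correlate at 0.940 or higher with the infected arrays of day 10, and those filed as water at day 10 at 0.888 or lower. With water arrays of day 5, those filed as water at day 10 correlate at 0.966 to 0.987 and those filed as infected at day 5 at 0.883 to 0.929. The 75th percentile minus the spike-in probes ran from -3.57 to -2.51 on arrays filed as infected at day 5. It ran from -2.04 to -0.93 on those filed as water at day 10, beside -4.38 to -3.24 in infected berries of day 10 and -1.68 to -0.84 in water berries of day 5. These values argue against wrongly attached scanner files for these 6 arrays, if infected berries resemble infected berries, though likeness alone does not prove what a sample was.

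The 75th percentile relative to the spike-in control probes, a signal outside the main measurement, was lower on infected arrays by -1.98. A few very bright transcripts taking the signal would leave the total level if summed probe signal followed the amount of RNA, which was not tested. The total differed by -1.36 relative to the spike-in probes, so under that assumption they are not the whole source. They may be part of it: the total differed less than the 75th percentile, and the share of the 100 brightest probes was higher by 10.1 percentage points (exact permutation tests within days, 6 infected and 6 water arrays, p = 0.005 for each). Whether loss of signal alone makes the genes that fell cannot be told apart here, since falls were 49.8% of calls at day 5 in the brightest of 3 equal parts of the probes, 61.7% in the middle and 45.0% in the dimmest, and 47.5%, 58.3% and 37.4% at day 10, but scaling to the 75th percentile centres bright probes and the floor of infected arrays lifts dim ones. Less grape RNA in the same mass of total RNA, for instance with fungal RNA in its place, may be a source: the difference was larger at day 10 than at day 5 by a further -0.76, which was not tested. It stays open because the spike-in amounts and the share of fungal RNA are not given in the sources used here, and a change within the berries goes with the groups in the same way.

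Rises were common among IDs beginning with XLOC, and the lowest signal above background, after scaling, lay higher on 5 of the 6 infected arrays than on any uninfected array, the exception being infected replicate 2 of day 5. With a common floor the excess of XLOC over VIT rises went from 10.3 to 0.193 percentage points at day 5, and a higher floor may account for it there, with that exception. That common floor, -3.555, is the highest of the 15 arrays and also removes real changes of dim probes below it. The smaller excess thus does not separate a higher floor from real rises. At day 10 the excess went from 19.9 to 12.8 points, so the common floor leaves most of it. Fungal RNA binding to some probes is a candidate explanation: 20 probes, 6 of them XLOC and 13 VIT, were off on all 9 uninfected and on on all 6 infected arrays, against 114 with the reverse. IDs not beginning with VIT were 35% of these 20, 7.36% of all tested and 11.3% of the other genes that rose at both days. Relative to the spike-in probes, the median of the 20 changed by 0.54 from day 5 to day 10, while the 75th percentile of infected arrays went from -2.97 to -3.93. Grape genes that switch on with infection would do the same, and the 6 XLOC probes are few of those that rose, so this cannot be told apart without probe sequences, which were not used here.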

How the results depend on the processing

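Counts of genes past the threshold were most often within 1.5 times under the other settings, and those that were not follow, by setting; unless said, the cause was not tested. With normexp, on the median signal, 7236 genes changed with infection at day 5, 455 in the difference between days and 3678 in water berries at day 5. With the value table's columns as given, which interchange 2 groups by construction, the counts were 815 and 3817 with infection at days 5 and 10, 6901 for infected berries of day 5 against untreated and 13327 for water berries of day 10, the overlap of infection calls was 68, the list's adjusted p at day 10 was 0.191 (0 lists called), VIT_02s0025g01090 at day 5 was at 0.26 in place of -4.38, and the calls of XLOC_007374 (2.01 and 0.41), VIT_03s0088g00010 (1.98), VIT_18s0041g01220 (-0.68) and VIT_07s0031g00870 (1.25) with infection were lost; with columns matched, chosen after seeing the data, no count past the threshold moved. Testing without a filter adds dim probes, 34369 probes in all. That setting gave 22521 genes changed with infection at day 10, 951 in the difference and 23936 for infected berries of day 10 against untreated. With scan as a block the difference called 3188, and with array weights water berries at day 5 called 11379. A threshold of 0.01 gave 437, 3486 and 4564 genes for the difference and for water berries at days 5 and 10. With camera's estimated correlation 0 lists were called in all but the comparisons of water with untreated berries. Spike-in scaling, chosen after seeing the data, gave 18557 genes with infection at day 5, 678 in the difference, 1580 and 1952 in water berries, an overlap of 17507 and a stilbene synthase median of -1.11 with infection at day 10. The common floor, and calls only where the higher group was above background, also chosen after seeing the data, moved no count past the threshold by 1.5 times.

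Counts of genes changed at least 2-fold moved more, in 30 cases apart from leaving out 1 array. With infection at days 5 and 10 they were 5614 and 8085. Among the 15879 probes detected on all 15 arrays, fewer than the 23454 tested, they were 2907 and 4668. The value table as given had 619 and 1328, and spike-in scaling 18557 and 20149. Normexp gave 2868 and a common floor 3739 at day 5, and no filter 16729 at day 10. For water berries at days 5 and 10, 2513 and 3120, a common floor gave 1563 and 2058, normexp 1024 and 1524, spike-in scaling 1580 and 1952, and probes detected on all 15 arrays 1397 and 1715, and for day 10 the value table as given 7416. The cause was not tested.

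Without 1 array, the difference between days called 896 to 2140 genes; the calls of infection ranged from 9023 to 11754 at day 5 and from 12333 to 14279 at day 10. The replicate block gave 11419 and 14450 genes with infection and 6049 for water berries of day 5 against untreated. That last pair of groups was the only 1 with every same-numbered correlation over 0.1, and its same-numbered arrays also shared scans. The block changed no call of the list or a named gene. Of 784 values of named genes under other settings, 730 kept direction and call, 53 lost the call and 1 turned. The mean over probes of a gene was not run, since each ID has 1 probe. Infected arrays have less signal over background, which limits what can be read of dim genes there.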

Other observations

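The counts of runs of neighbouring IDs, and of other splits of the arrays, were planned before their results were seen; the comparison of infection with incubation was chosen after.

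Genes that changed with infection lay side by side. Along 21728 tested VIT IDs in number order within the same leading part of the ID, 25 runs of at least 5 neighbours rose at least 2-fold with infection at day 5, where 1000 shuffles of the calls gave a mean of 0.878 runs and at most 8 (one-sided permutation p = 0.001, the smallest they can give). At day 10 there were 29 runs of rises, against at most 13 in shuffles. Falls made 3 runs at day 5, against at most 2, and 11 at day 10, against at most 6. The longest run at day 5 held 27 IDs and lay in a stilbene synthase range; of the 25 runs, 22 held no ID of these ranges, the longest of them with 12 IDs, from VIT_12s0057g00040 to VIT_12s0057g00170, chosen after its values were seen. Chance placement was thus exceeded in all 4 sets. Shared regulation of tandem gene families may account for the runs, and so may probes that bind near-identical copies; the 25 runs at day 5 do not separate these.

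The infection effect at day 5 and the change of water berries from day 0 to day 10 share no arrays. They correlated across genes at r = 0.42 (Spearman's rho 0.26), and at 0.40 without the stilbene synthases. Of the genes called in both, 1937 rose and 1343 fell in both, where independent lists would share 733 and 889, and 389 rose with infection and fell in water berries, where 792 would be shared by chance. For infection at day 10 and water berries at day 5, r was 0.06 (rho 0.08), and 1383 genes rose and 1071 fell in both, where independent lists would share 939 and 764. Whether this describes an earlier onset in infected berries of what water berries do later was not tested.

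For each of the 6 comparisons of 2 groups, the 6 arrays make 10 splits, too few for a share under 0.05. With infection at day 5 and at day 10, 1 split, the real one, gave as many genes as the 10907 and 13992 found, and the highest of the others gave 0. Against untreated berries the real counts were 13312, 15854, 5697 and 6958, and the highest others 0, 0, 1 and 2. For the stilbene synthase median, the real values 3.39 and 1.25 with infection stood beside highest others of 1.74 and 0.86, and the 4 comparisons with untreated berries, 6.62, 6.69, 3.06 and 5.51, beside 2.80, 2.92, 2.01 and 2.47. For the overlap of infection calls, 1 of 100 drawn splits, the real one with 9274 genes, was as large and the others gave 0. Each of the other 99 mixed the arrays of at least 1 day, and a mixed day called 0 genes, so this count says nothing on how far the days share genes.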
